A study of Mus musculus with 6 samples.

How the data were processed

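Gene expression was measured by RNA sequencing in subcutaneous white adipose tissue from 3 control mice with floxed Nampt alleles and 3 ANKO mice in which adiponectin-Cre had removed Nampt from adipocytes. Per the labels' protocols, tissue was frozen in liquid nitrogen, RNA was extracted with Qiazol and RNeasy columns, and ribosomal RNA was depleted with the Ribo-Zero Gold kit. Per the submitters' processing notes, the tools were STAR 2.0.4b, Subread and featureCounts 1.45 with the mouse genome build GRCm38. The annotation release and the strand setting of the counting are not given in the sources used here. The deposited values are raw, not normalised read counts per gene symbol, with 1 column per mouse, and the comparison groups were taken from the sample titles. The series design gives 3 mice per group.

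The deposited table held 40757 lines, of which 329 repeated another line exactly (88 of them with counts above 0) and were removed, leaving 40428 features. Several lines with different counts existed for 105 symbols (211 lines), and these were kept as separate features. A spreadsheet-like date stood in place of the symbol in 26 lines, which were kept under that name. Of 40322 distinct symbols, 40221 were found in the GENCODE M21 annotation of GRCm38, which gave gene positions, exons and overlaps. Library totals were 19748962 to 23860596 counts. The most abundant feature, Gm26917, took 4.32% to 5.42% of the counts, the top 10 features 13.7% to 16.8% and genes of the mitochondrial genome 2.64% to 3.65%.

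The counts were tested with edgeR 4.0.16 in R 4.3.3. Features were kept by filterByExpr on the 2 groups (minimum count 10, minimum total count 15), which left 19272. Library sizes were scaled by TMM, dispersions were estimated with robust weighting (common biological coefficient of variation 0.228), and ANKO was compared with control by the quasi-likelihood F test with robust=TRUE. Adjusted p-values are Benjamini-Hochberg values over all genes tested unless said to be adjusted over the list alone, and the threshold was 0.05. Log2 fold changes are ANKO over control, and each standard error is the fold change divided by the square root of F. CPM values are TMM-scaled and given as mean ± SD over 3 mice. The median standard error was 0.186 on the log2 scale. TMM, RLE, upper-quartile and no scaling moved the median log2 fold change of all genes by at most 0.03, and 66% to 69.3% of calls were lower under each of them.

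Before the data were examined, the test, the alternatives, 33 gene lists and the rule for naming genes were fixed. The rule took Nampt, the 12 genes with the largest rises and the 12 with the largest falls among called genes with a mean of at least 1 CPM, fully separated groups and no clone-type symbol, and from each list the 3 called members with the smallest p, or the 1 member with the smallest p where none was called. This gave 70 genes, of which 1 is not reported here. The lists cover NAD synthesis and consumption, adipocyte identity, PPARG phosphorylation targets, thermogenesis, lipid, glucose, amino acid and mitochondrial pathways, insulin signalling, matrix, inflammation, interferon, stress, p53, clock, proliferation and ribosomal genes, and markers of 11 other cell types. Of 729 listed genes, 695 list places were tested, covering 681 distinct genes with 14 in more than 1 list, and 5 (Pnp, Ighd, Dlk1, Flg and Ahsp) matched no feature name used here. Symbols with several different lines carried an added line number and could not match, so these 5 are not shown to be absent. Lists were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry (limma 3.58.1), each adjusted over the 33 lists. In addition 4 lists, of NRF2 targets, lysosomal genes, adipocyte G protein-coupled receptors and amino acid and solute carriers, were written after the results had been seen. Their tests were adjusted over these 4 lists alone.

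The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, robust=FALSE, no low-count filter, a filter of at least 1 CPM in 3 samples, removal of mitochondrial-genome and ribosomal RNA genes, the replicate number as a block, and leaving out each library in turn. A covariate for skeletal muscle RNA and a removal of trends with GC content and transcript length (both known for 99.4% of tested features) were added after seeing the data. All 10 ways of dividing the 6 libraries 3 against 3 were refitted.

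The steps were tested on simulated data, with 200 of 18946 genes changed. A further list of 25 genes was shifted 1.5-fold and also counted as changed. Counts were drawn from negative binomial distributions with the mean levels, dispersions and library sizes of these libraries. Genes were drawn independently of each other, and changed genes had a mean of at least 1 CPM. Genes of lower counts and variation shared between genes, as from muscle RNA, were therefore not covered. For this comparison the test called 10.4% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 80.3% of those changed 4-fold, and 7 of 106 calls (6.6%) were false. Most changes of 1.5-fold would therefore be missed with 3 mice per group. A 2-sided permutation of 3 against 3 cannot give a p under 0.1, so single genes rest on the spread that the model shares across genes.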

Results

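RNA was sequenced from the subcutaneous white adipose tissue of 6 C57BL/6J mice kept on regular chow at room temperature. In 3 mice the gene for nicotinamide phosphoribosyltransferase, Nampt, had been deleted in adipocytes by crossing floxed Nampt to a Cre recombinase driven by the adiponectin promoter (adipocyte-specific Nampt knockout, ANKO). The 3 control mice carried the floxed alleles. Whole tissue was used, so the libraries hold RNA of adipocytes and of the vascular, stromal, immune and nerve cells around them. Total counts were 22588171, 19748962 and 20304187 in controls 1, 2 and 3 and 23860596, 23735655 and 20419821 in ANKO 1, 2 and 3. No pair of libraries held the same counts within sampling noise, with a chi-square per degree of freedom of 33.7 to 97.2 over the pairs. All 6 libraries had the counts of female mice, with 30146 to 40280 for Xist and 0 for the Y-linked Ddx3y.

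The comparison asks how the loss of Nampt from adipocytes altered gene expression in this fat depot. Nampt (chromosome 12, 32819545 to 32853349, plus strand) makes nicotinamide mononucleotide, the rate-limiting step of NAD salvage. Its normalised count was 87.9 ± 4.77 CPM (counts scaled to library size; SD, n = 3) in controls and 48.6 ± 1.59 CPM in ANKO. The control values were 83.6, 93.0 and 87.0 CPM and the ANKO values 48.6, 50.2 and 47.0 CPM, so every ANKO library lay below every control library. The log2 fold change was -0.85 (SE 0.0776, adjusted p = 0.00416), or 0.553 of the control level. The tissue also contains cells without the deletion, and the floxed exons are not given in the sources used here, so the count covers the whole gene. The smallest p in the NAD synthesis and salvage list was that of Nnmt, the nicotinamide N-methyltransferase, which fell from 39.4 ± 4.92 to 7.96 ± 0.308 CPM (log2 fold change -2.31, SE 0.126, adjusted p = 0.000869). Nampt and Nnmt were the 2 of 24 measured members of that list that fell, 3 fell when adjusted over the list alone, and none rose. The same 2 genes were called after leaving out any 1 library. None of 22 NAD consumers, the sirtuins, poly(ADP-ribose) polymerases and NAD glycohydrolases, passed the test over all genes or adjusted over the list alone. The consumer with the smallest p was Parp4 (98.3 ± 1.42 against 86.8 ± 2.33 CPM, log2 fold change -0.18, adjusted p = 0.320).

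**Figure D1:**
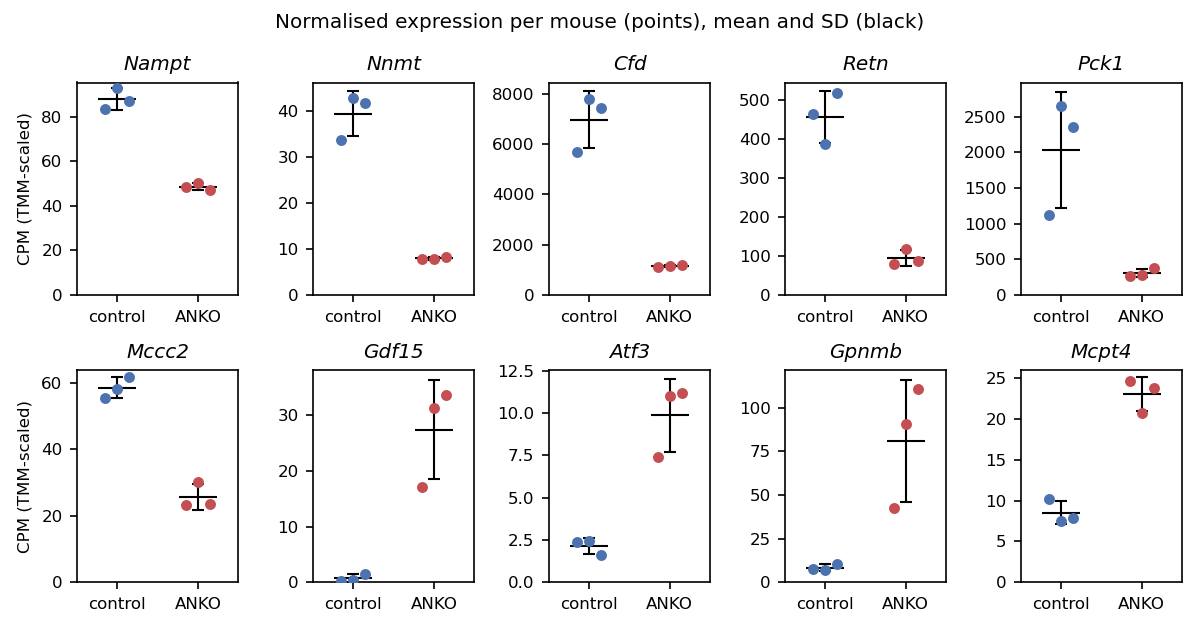
Normalised expression in CPM (vertical axis, from 0) of 10 genes in each of the 3 control and 3 ANKO mice, with points for mice and black bars for the mean and SD. Nampt, Nnmt, Cfd, Retn, Pck1 and Mccc2 were lower in all 3 ANKO mice than in all 3 controls, and Gdf15, Atf3, Gpnmb and Mcpt4 were higher.

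Across 19272 genes tested, 94 were higher and 212 lower in ANKO tissue at an adjusted p under 0.05. Of these, 56 rose and 140 fell by at least 2-fold. In all 306 the 3 values of one group lay above the 3 of the other, against 19.4% of the tested genes and the 10% that chance gives for 3 against 3. The test that called the 306 favours such genes, so their separation is not further evidence. The counts of higher and of lower genes both moved with single libraries. The higher genes numbered 35 without control 1, 26 without control 2, 35 without control 3, 41 without ANKO 2 and 20 without ANKO 3. The lower genes numbered 92 without control 2, 110 without control 3, 93 without ANKO 1, 113 without ANKO 2 and 55 without ANKO 3. All 306 kept their direction in each of these fits. Because their groups did not overlap, leaving out 1 library could hardly turn a direction, so this is not evidence of stability. The libraries also differed in skeletal muscle RNA, and 19 muscle marker genes made up 1.24%, 0.368% and 1.97% of the counts in controls 1 to 3 and 3.72%, 0.643% and 0.0304% in ANKO 1 to 3. With the muscle signal as a covariate, an alternative chosen after seeing the data, 50 genes were higher and 111 lower. Of the 55 named genes past the threshold, 15 stayed past it whichever library was left out: Nampt, Nnmt, Cfd, Retn, Mccc1, Mccc2, Pfkfb3, Mcam, Wfdc21, Cxcl11, Atf3, Slc7a11, Mcpt4, Phospho1 and Myl3. Besides Nampt, 17, 35 and 24 of the named calls were lost without control 1, 2 and 3 and 15, 22 and 31 without ANKO 1, 2 and 3.

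Several adipokine and other adipocyte genes fell. Cfd (chromosome 10, 79890853 to 79892655), which encodes the adipokine adipsin, fell from 6970 ± 1131 to 1148 ± 25.5 CPM (log2 fold change -2.60, SE 0.154, adjusted p = 0.000869). Retn (chromosome 8, 3655770 to 3660110), which encodes resistin, fell from 456 ± 66.5 to 94.8 ± 20.3 CPM (log2 fold change -2.27, SE 0.178, adjusted p = 0.00252). Acvr1c, the activin receptor ALK7, fell to 0.323 of the control level (log2 fold change -1.63, SE 0.182, adjusted p = 0.010). In the adipocyte identity and adipokine list 7 of 25 measured members fell, 12 when adjusted over the list alone, and none rose, with a median log2 fold change of -0.68. The other 4, named here after their values were seen, were adiponectin (Adipoq, -1.39), the lipid droplet coat protein Plin1 (-1.24), Acsl1 (-1.34) and Nrip1 (-0.72). The 7 became 4 without control 3 and 3 without control 2 or ANKO 3. Of 17 genes known to respond to phosphorylation of PPARG, 4 fell and 1 rose, and 6 fell and 1 rose when adjusted over the list alone. Cfd and Adipoq were 2 of the 4 and belong to both lists. Car3, an abundant carbonic anhydrase of adipocytes, fell from 6515 ± 1405 to 2170 ± 353 CPM (log2 fold change -1.59, SE 0.198, adjusted p = 0.0109), and Selenbp1, named after its value was seen, fell by 1.19 on the log2 scale. The imprinted gene Peg10 rose from 10.5 ± 0.201 to 41.3 ± 13.0 CPM (log2 fold change 1.98, SE 0.238, adjusted p = 0.0124). The 4 falls became 2 without control 2 and 1 without ANKO 3, and Peg10 was not called without control 2, control 3 or ANKO 3 (highest adjusted p = 0.0732).

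Several genes of triglyceride storage and of insulin signalling were lower. Pck1 (chromosome 2, 173153048 to 173159273), the cytosolic phosphoenolpyruvate carboxykinase used for glyceroneogenesis in fat, fell from 2035 ± 812 to 306 ± 58.4 CPM (log2 fold change -2.73, SE 0.346, adjusted p = 0.0189). Gpat3, a glycerol-3-phosphate acyltransferase, fell from 85.2 ± 25.3 to 22.4 ± 4.40 CPM (log2 fold change -1.93, SE 0.238, adjusted p = 0.0159). G0s2, the inhibitor of adipose triglyceride lipase, fell from 69.6 ± 13.4 to 29.7 ± 4.36 CPM (log2 fold change -1.23, SE 0.166, adjusted p = 0.0148). With Plin1 these were the 4 of 20 measured members of the triglyceride synthesis and lipolysis list that fell, 12 fell when adjusted over the list alone, and none rose. The 4 became 1 without control 2, ANKO 1 or ANKO 3. Outside this list the lipid droplet coat gene Plin2, named after its value was seen, rose from 159 ± 17.5 to 642 ± 236 CPM (log2 fold change 2.01, SE 0.274, adjusted p = 0.0234). The monoacylglycerol acyltransferase Mogat2 rose as well (log2 fold change 3.33, adjusted p = 0.0134). In the insulin signalling list 3 of 22 fell, among them the phosphodiesterase Pde3b (342 ± 66.1 to 155 ± 18.5 CPM) and the transcription factor Foxo1 (148 ± 6.18 to 103 ± 0.453 CPM). The log2 fold changes of Pde3b and Foxo1 were -1.14 and -0.52 with adjusted p = 0.0154 and 0.0152, and 7 of the list fell and 1 rose when adjusted over the list alone. None of the 3 was called without control 2, ANKO 1 or ANKO 3. Pfkfb3, which makes the glycolytic activator fructose 2,6-bisphosphate, fell from 791 ± 131 to 328 ± 9.48 CPM (log2 fold change -1.27, SE 0.134, adjusted p = 0.00665) and was the 1 of 21 glucose uptake and glycolysis genes past the test. When adjusted over the list alone, 4 of these 21 rose and 1 fell. De novo lipogenesis had none of 22 members past the test and 1 that rose when adjusted over the list alone. Its smallest p was that of Mid1ip1, at 14.8 ± 3.01 and 41.6 ± 15.6 CPM in control and ANKO (log2 fold change 1.49, SE 0.294, adjusted p = 0.0756), and DESeq2 called 3 members.

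Of 21 measured genes of branched-chain amino acid breakdown, 8 fell over all genes and 19 when adjusted over the list alone. All 21 had a negative log2 fold change, with a median of -0.66, while as a set the list had adjusted p = 0.229 with an estimated correlation and adjusted p = 0.0555 by fry. Mccc1 and Mccc2, the 2 subunits of methylcrotonyl-CoA carboxylase in leucine breakdown, fell from 109 ± 14.6 to 53.1 ± 2.57 CPM (log2 fold change -1.04, SE 0.108, adjusted p = 0.00618) and from 58.6 ± 3.21 to 25.7 ± 4.00 CPM (log2 fold change -1.19, SE 0.122, adjusted p = 0.00618). Aldh6a1, the methylmalonate semialdehyde dehydrogenase of valine breakdown, fell from 283 ± 59.2 to 111 ± 5.94 CPM (log2 fold change -1.35, SE 0.153, adjusted p = 0.00837). The 8 became 5 without control 2 or ANKO 1 and 2 without ANKO 3. Other mitochondrial pathways showed few or no calls. In fatty acid beta-oxidation none of 24 members passed the test over all genes with edgeR or limma-voom, while DESeq2 called 6. There 13 had an unadjusted p under 0.05, 10 fell and 1 rose when adjusted over the list alone, and the median log2 fold change was -0.39. Its smallest p was that of Ech1 (127 ± 18.3 against 84.5 ± 10.4 CPM, log2 fold change -0.59, SE 0.133, adjusted p = 0.0872). Of 76 nuclear-encoded oxidative phosphorylation subunits, 1 fell, over all genes and adjusted over the list alone. This was Ndufb3 of complex I (42.8 ± 4.56 to 27.1 ± 1.27 CPM, log2 fold change -0.66, SE 0.105, adjusted p = 0.0262), which was called in only 1 of the 6 fits that left out a library (highest adjusted p = 0.125, without ANKO 3). None of the 13 subunits encoded by the mitochondrial genome passed over all genes or adjusted over the list alone. The one with the smallest p, mt-Nd2, stood at 2188 ± 312 and 2996 ± 640 CPM in control and ANKO (adjusted p = 0.338). None of 26 pyruvate and tricarboxylic acid cycle genes passed over all genes and 1 fell when adjusted over the list alone, and its smallest p was that of Suclg2 (log2 fold change -0.60, SE 0.128, adjusted p = 0.0706).

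Several genes of the integrated stress response and mitochondrial stress response rose. In this list 7 of 21 measured members rose, 10 when adjusted over the list alone, and none fell. The stress-inducible transcription factor Atf3 (chromosome 1, 191170296 to 191218039) rose from 2.14 ± 0.471 to 9.88 ± 2.15 CPM (log2 fold change 2.20, SE 0.255, adjusted p = 0.00847). The cystine transporter Slc7a11 rose from 11.7 ± 1.88 to 35.1 ± 5.94 CPM (log2 fold change 1.59, SE 0.172, adjusted p = 0.00717), and Atf5, a regulator of the mitochondrial unfolded protein response, from 97.0 ± 5.42 to 271 ± 78.6 CPM (log2 fold change 1.48, SE 0.20, adjusted p = 0.0171). The stress hormone Gdf15 (chromosome 8, 70629393 to 70632456) had the largest log2 fold change of the named genes, rising from 0.759 ± 0.745 to 27.4 ± 8.91 CPM (log2 fold change 5.20, SE 0.692, adjusted p = 0.0331). Its call was lost without control 2, ANKO 2 or ANKO 3 (highest adjusted p = 0.142). The other 3 that rose, named after their values were seen, were Atf4 (log2 fold change 0.55), Ddit3 (0.90) and the mitochondrial folate enzyme Mthfd2 (1.00). The 7 became 4 without control 3, 3 without control 1, control 2 or ANKO 2, and 2 without ANKO 3. Of 17 p53 targets and senescence genes 1 rose and 3 when adjusted over the list alone. The 1 was the growth arrest gene Gadd45a (6.52 ± 0.926 to 14.4 ± 2.16 CPM, log2 fold change 1.14, SE 0.174, adjusted p = 0.0225), not called without control 2, control 3, ANKO 2 or ANKO 3 (highest adjusted p = 0.0935). Of 27 brown and beige thermogenic genes 2 rose, the fatty acid elongase Elovl3 (0.262 ± 0.124 to 5.54 ± 3.29 CPM, log2 fold change 4.39, SE 0.577, adjusted p = 0.0134) and the acyl-CoA thioesterase Acot11 (6.56 ± 0.783 to 33.4 ± 12.5 CPM, log2 fold change 2.35, SE 0.268, adjusted p = 0.0107), and 3 rose when adjusted over the list alone. Elovl3 was not called without any 1 of the controls (highest adjusted p = 0.0561) and Acot11 was not called without control 2 (adjusted p = 0.0659).

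**Figure D2:**
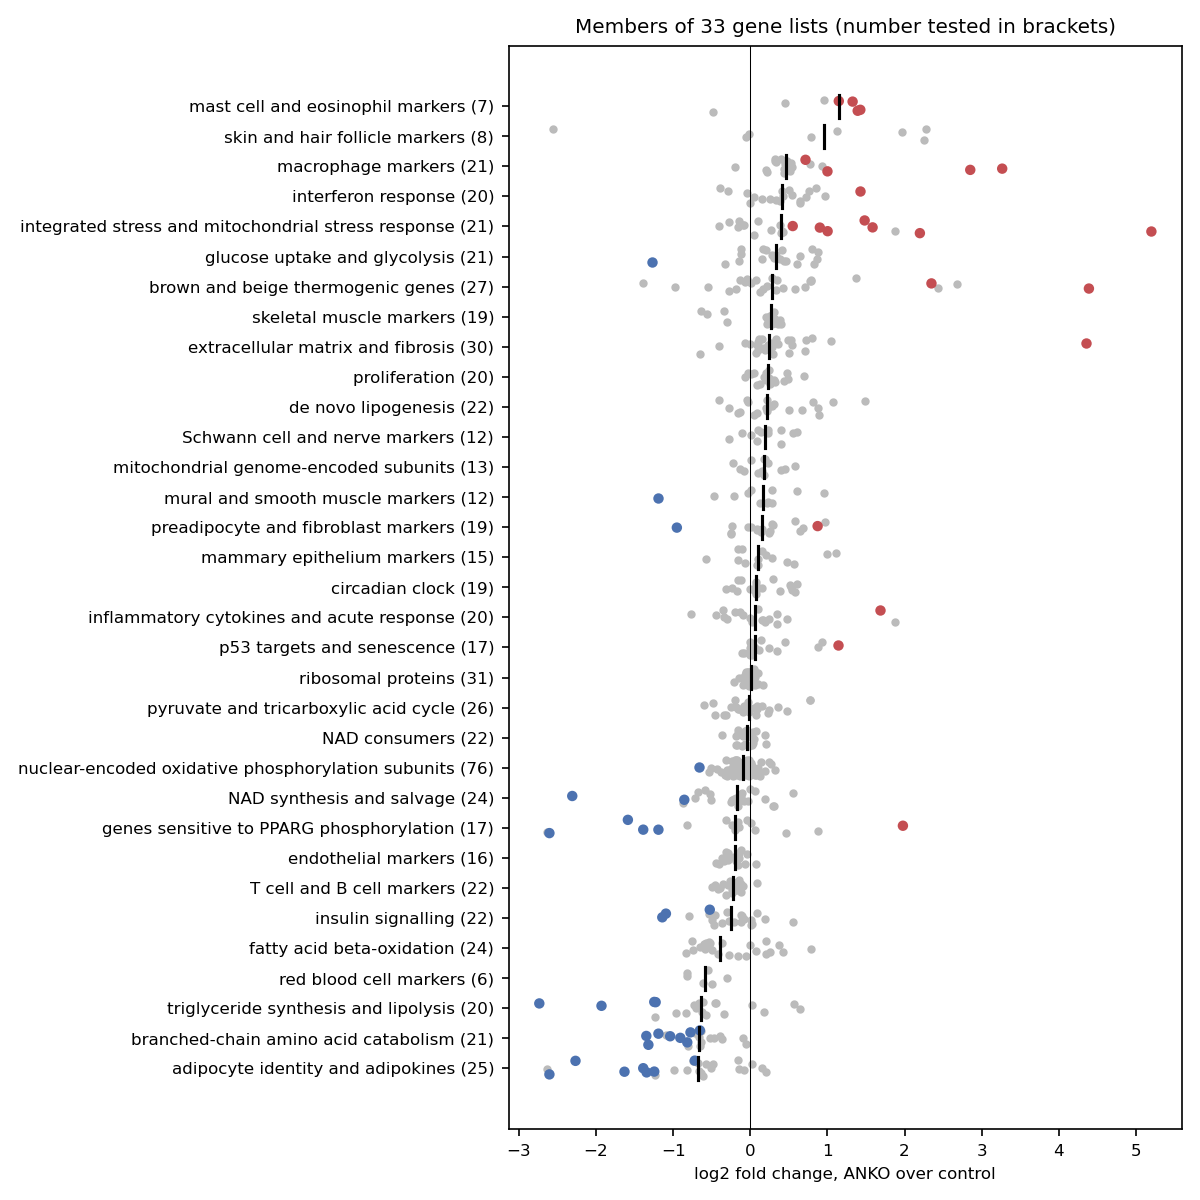
Log2 fold change, ANKO over control (horizontal axis), of the measured members of 33 gene lists, with the number tested in brackets. Red and blue points are members that rose or fell at an adjusted p under 0.05, grey points did not pass, and black bars are list medians, from -0.68 for adipocyte identity to 1.15 for mast cell and eosinophil markers.

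Several markers of macrophages and mast cells rose. Of 21 macrophage markers 4 rose and 12 when adjusted over the list alone, with none lower. Gpnmb (chromosome 6, 49036546 to 49070929), a glycoprotein of lipid-laden macrophages, rose from 8.43 ± 1.86 to 81.1 ± 34.9 CPM (log2 fold change 3.27, SE 0.409, adjusted p = 0.0285). The macrophage receptor Trem2 rose from 1.28 ± 0.619 to 9.36 ± 4.74 CPM (log2 fold change 2.85, SE 0.497, adjusted p = 0.0449), Adgre1, the gene of the F4/80 antigen, from 20.4 ± 0.444 to 40.9 ± 6.80 CPM (log2 fold change 1.00, SE 0.128, adjusted p = 0.0119), and the lysosomal protease Lgmn from 50.4 ± 6.02 to 82.8 ± 11.9 CPM (log2 fold change 0.72, SE 0.128, adjusted p = 0.0405). The 4 became 1 without control 1, control 3, ANKO 2 or ANKO 3 and 0 without control 2. Of 7 measured mast cell and eosinophil markers 4 rose and 5 when adjusted over the list alone. The mast cell proteases Mcpt4 (8.53 ± 1.46 to 23.0 ± 2.06 CPM, log2 fold change 1.43, SE 0.155, adjusted p = 0.00717), Cma1 (log2 fold change 1.39, SE 0.184, adjusted p = 0.0133) and Tpsb2 (log2 fold change 1.33, SE 0.179, adjusted p = 0.0139) were joined by Cpa3 (1.15), named after its value was seen. The 4 became 1 without control 2 and 2 without ANKO 2 or ANKO 3. Of 30 extracellular matrix genes 1 rose, the macrophage metalloelastase Mmp12 (0.964 ± 0.310 to 19.97 ± 12.5 CPM, log2 fold change 4.35, SE 0.585, adjusted p = 0.0281), and 3 rose when adjusted over the list alone. Of the 30, 27 had a positive log2 fold change, with a median of 0.25, and DESeq2 called 4. As a set the matrix list had adjusted p = 0.144 by fry. Of 20 inflammatory cytokine genes 1 rose, Spp1 or osteopontin (1.06 ± 0.379 to 3.40 ± 0.568 CPM, log2 fold change 1.68, SE 0.322, adjusted p = 0.0499), and 2 rose and 1 fell when adjusted over the list alone. Of 20 interferon response genes 1 rose, Rsad2 or viperin (15.95 ± 3.62 to 42.8 ± 10.7 CPM, log2 fold change 1.42, SE 0.235, adjusted p = 0.0379), and 8 rose and 1 fell when adjusted over the list alone. The call was lost in 4 of the 6 fits that left out a library for Mmp12 and in 5 for Spp1 and Rsad2, with highest adjusted p = 0.145 without control 3, 0.156 without ANKO 2 and 0.127 without ANKO 3.

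Other cell types of the depot showed few calls. Of 19 preadipocyte and fibroblast markers 1 rose and 1 fell, and 4 rose and 1 fell when adjusted over the list alone. The Wnt modulator Sfrp2 rose from 28.7 ± 1.81 to 52.6 ± 8.73 CPM (log2 fold change 0.87, SE 0.131, adjusted p = 0.0203) and the actin-severing protein Gsn fell from 4458 ± 726 to 2306 ± 275 CPM (log2 fold change -0.95, SE 0.160, adjusted p = 0.0315). Each was called in only 1 of the 6 fits that left out a library, with highest adjusted p = 0.0716 without control 1 and 0.142 without ANKO 3. Of 12 mural and smooth muscle markers 1 fell, over all genes and adjusted over the list alone. This was the adhesion molecule Mcam, from 158 ± 10.8 to 68.8 ± 11.9 CPM (log2 fold change -1.20, SE 0.130, adjusted p = 0.00717). The lists of endothelial markers (16 measured), T and B cell markers (22), Schwann cell and nerve markers (12), red blood cell markers (6), mammary epithelium (15), skin and hair follicle (8) and skeletal muscle (19) had no member past the test over all genes or adjusted over the list alone. Neither did the circadian clock (19), proliferation (20) and ribosomal protein (31) lists. The members with the smallest p in these 10 lists were Robo4, Cd3d, S100b, Alas2, Wfdc18, Tchh, Myh7, Bhlhe40, Mcm2 and Rps19, with adjusted p = 0.164, 0.169, 0.355, 0.244, 0.561, 0.268, 0.858, 0.110, 0.463 and 0.309. Over all 15 lists without a called member, 34 of 275 measured members had an unadjusted p under 0.05, DESeq2 called 13 and limma-voom called 0. Endothelial markers were negative in 15 of 16 and T and B cell markers in 21 of 22, with median log2 fold changes of -0.20 and -0.22. Red blood cell markers were negative in 6 of 6 (median -0.58) and proliferation genes positive in 18 of 20 (median 0.24). Without ANKO 3 the proliferation median was -0.13.

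**Figure D3:**
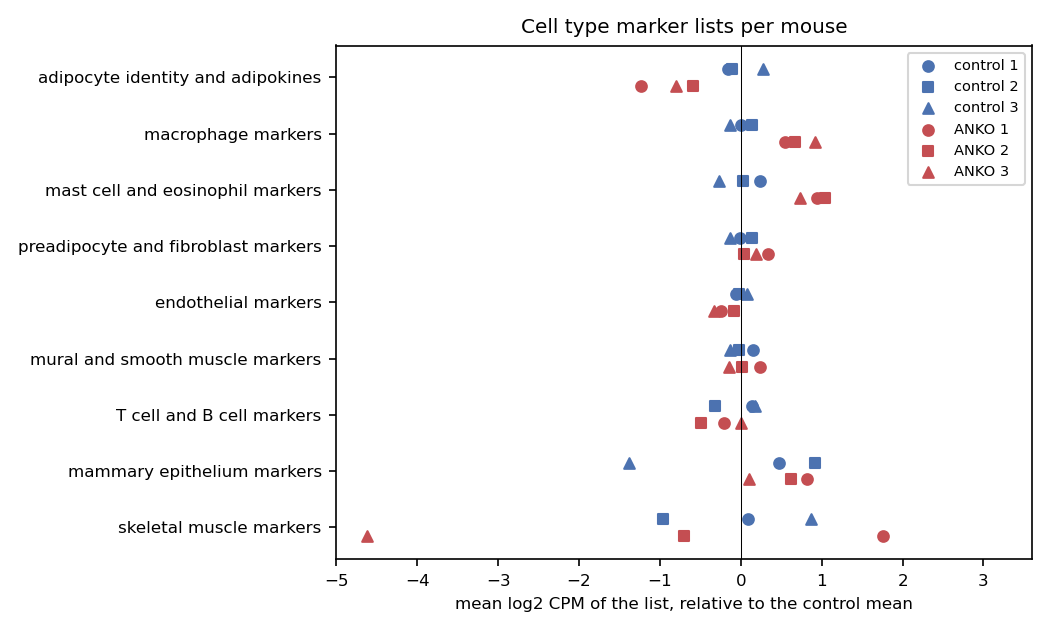
Mean log2 CPM of 9 lists of cell type markers in each mouse, relative to the control mean (horizontal axis), with circles, squares and triangles for replicates 1, 2 and 3 and blue and red for control and ANKO. The 3 ANKO mice lay below the controls for adipocyte markers and above them for macrophage and mast cell markers, while the skeletal muscle list ranged from -4.62 in ANKO 3 to 1.75 in ANKO 1.

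Several of the largest changes fell outside the 33 lists fixed beforehand. Among the rises were the vacuolar ATPase subunit Atp6v0d2 (log2 fold change 4.25, SE 0.691, adjusted p = 0.0418), the monoacylglycerol acyltransferase Mogat2 (3.33, SE 0.414, adjusted p = 0.0134), the klotho family member Lctl (2.97, SE 0.344, adjusted p = 0.0183), the phospholipase Pla2g2e (2.92, SE 0.457, adjusted p = 0.0245) and monoamine oxidase A, Maoa (14.3 ± 0.553 to 95.8 ± 34.0 CPM, log2 fold change 2.74, SE 0.291, adjusted p = 0.0133). The phosphatase gene Phospho1 (3.38, SE 0.264, adjusted p = 0.00228) and the myosin light chain Myl3 (3.69, SE 0.480, adjusted p = 0.0128) rose and were called whichever library was left out. Myl3 is also a muscle gene, but its level did not follow the muscle signal. It stood at 4.41 and 7.06 CPM in ANKO 3 and ANKO 2, where muscle genes made up 0.0304% and 0.643% of the counts, and at 0.131 and 0.464 CPM in controls 1 and 3, with 1.24% and 1.97%. With the skeletal muscle score as covariate, chosen after seeing the data, the log2 fold change of Myl3 was 3.70 (adjusted p = 0.0342). In that fit Lctl, Ncam2, Mup10 and Pon1 lost their calls (adjusted p = 0.0525, 0.0840, 0.104 and 0.0730). Their log2 fold changes with the covariate were 2.91, -3.92, -2.81 and -2.76, close to 2.97, -3.85, -2.82 and -2.56 without it. Among the falls were the lactate receptor Hcar1 (84.1 ± 34.8 to 11.4 ± 0.913 CPM, log2 fold change -2.89, SE 0.306, adjusted p = 0.0133), the neutral amino acid transporter Slc7a10 (164 ± 50.3 to 32.4 ± 3.62 CPM, log2 fold change -2.34, SE 0.244, adjusted p = 0.0107) and the imprinted gene Nnat (209 ± 32.3 to 35.3 ± 13.2 CPM, log2 fold change -2.57, SE 0.291, adjusted p = 0.0153). The adhesion molecule Ncam2 (-3.85), the major urinary protein gene Mup10 (-2.82), Wfdc21 (-2.74) and the signalling regulator Rgs7 (-2.57) also fell, with adjusted p = 0.0376, 0.0469, 0.00618 and 0.0179. So did paraoxonase Pon1 (-2.56), the acyl-CoA synthetase family gene Acsm5 (-2.48) and Cxcl11 (-2.42), a chemokine gene annotated as a polymorphic pseudogene, with adjusted p = 0.0446, 0.0469 and 0.00471. Of these 17 genes, Phospho1, Myl3, Wfdc21 and Cxcl11 kept their calls in all 6 fits that left out a library, and the highest adjusted p among the others was 0.194 for Acsm5 without ANKO 2. Mup10 belongs to a family of near-identical genes among which reads can be divided, so its value is uncertain. Exons of 11 named genes overlap exons of another gene over at least 10% of their length, and the strand setting of the counting is not given in the sources used here. Their values can therefore include the partner's reads or lack reads shared with it. The overlap was 89.6% for Phospho1 with Zfp652 on the same strand and 41.7% for Cxcl11 with Gm2673, and 12.9% to 30.0% for Gpat3, Mid1ip1, Acot11, Gadd45a, Spp1, Aldh6a1, Slc7a10, Sfrp2 and Alas2.

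Taken as sets against all other genes, 22 of the 33 lists passed camera with a preset correlation of 0.01 between genes, 11 upwards and 11 downwards. With an estimated correlation 5 lists had an unadjusted p under 0.05 and none passed, the lowest being adjusted p = 0.229 with an estimated correlation. Fry, which tests whether the genes of a list move on balance one way, passed 2 lists, NAD synthesis and salvage (lower) and mast cell and eosinophil markers (higher), each with adjusted p = 0.0217. The NAD list includes Nampt, the deleted gene itself, so part of its fall was given by the design. Only Nampt and Nnmt of its 24 measured members were called, and its median log2 fold change was -0.17. The list was not tested without Nampt. The sign of the median differed from that of the mean for ribosomal proteins (0.01 and -0.00105) and from camera's direction for mural and smooth muscle and skeletal muscle markers.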

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

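The settings with a muscle covariate and with GC and length trends removed were chosen after the results had been seen. All 306 called genes kept their direction in each alternative that tested them (303 of 303 under the filter of at least 1 CPM in 3 samples), and Nampt stayed past the threshold in all of them, with a log2 fold change of -0.89 to -0.81 over the fits that left out a library. The groups of the 306 did not overlap, so leaving out a library or changing the scaling could hardly turn their direction. Genes higher in ANKO (94) numbered 371 with DESeq2, 62 with limma-voom, 167 without a low-count filter, 50 with the muscle covariate and 20 to 107 over the fits that left out 1 library. Genes lower in ANKO (212) numbered 482 with DESeq2, 111 with the muscle covariate and 55 to 221 over the fits that left out 1 library. DESeq2 and the fit without a filter tested 29178 and 29188 features and the left-out fits used fewer samples; beyond that the cause was not tested. The share of lower calls was 46.5% without ANKO 1. With the replicate block 62 genes were higher and 145 lower, of which 47 and 125 were called without it. The values did not show a pairing by replicate number. The deviations of same-numbered libraries correlated at 0.0746, -0.0333 and -0.0435. Control 1 and ANKO 1 correlated best with each other, while 2 of 3 controls correlated best with another number. Correlations this weak cannot exclude that same-numbered mice were related. Of the 54 named calls besides Nampt, all were kept with DESeq2, RLE and upper-quartile scaling and without mitochondrial and ribosomal RNA genes. The block lost 17, limma-voom 14, the muscle covariate 11 (among them Gdf15, Lctl, Ncam2, Mup10, Pon1, Ndufb3, Foxo1, Spp1, Gadd45a and Gsn), the fit without a filter 9, robust=FALSE 5, and the stricter filter and the GC and length fit 1 each. The named genes that lost their calls with the muscle covariate kept similar log2 fold changes. Examples, with and without the covariate, were Gdf15 (5.04 and 5.20), Spp1 (1.76 and 1.68), Foxo1 (-0.53 and -0.52) and Gsn (-0.88 and -0.95). For the gene lists, direction was the one that camera or fry gave, which can turn while the median log2 fold change keeps its sign. It reversed for ribosomal proteins with fry (median 0.0102, as with camera), with the block (0.0134) and with the muscle covariate (0.00558), and for skeletal muscle markers with the muscle covariate (0.0621, against 0.27 without it), with the median positive in each. Over the fits that left out 1 library it reversed in 1 or more for these lists, given with the range of their medians over the 6 fits: ribosomal proteins (-0.0486 to 0.0653), nuclear-encoded oxidative phosphorylation subunits (-0.19 to 0.04305), mitochondrial genome-encoded subunits (-0.0311 to 0.41), pyruvate and tricarboxylic acid cycle (-0.15 to 0.14), proliferation (-0.13 to 0.39), mural and smooth muscle markers (-0.0137 to 0.26), skeletal muscle markers (-1.84 to 0.84), and mammary epithelium markers (-0.21 to 0.52). Mural and skeletal muscle medians were positive in the full fit (0.17 and 0.27) and where the direction turned (0.26 without control 1 and 0.24 without ANKO 3 for mural, 0.84 without ANKO 3 for skeletal muscle). Among genes the log2 fold change of Myh7 changed sign (-1.36 to 0.54). The cause was not tested. Of the 22 lists passing camera with the preset correlation, 22 were lost with an estimated correlation and 20 with fry. At these depths the simulated recovery of 2-fold changes was 53.7%, so a gene that missed the threshold is not shown to be the same in both groups.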

Other observations

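The tests of adipocyte share, macrophage kind, copies near Adipoq and NRF2 targets were chosen after the results had been seen, as were the 4 further gene lists and the genes named from them; the refits of the other splits were planned.

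Several receptors through which adipocytes sense metabolites and hormones were lower in ANKO tissue. In a list of 18 adipocyte G protein-coupled receptors, some of which are also in lists fixed before, 9 fell and none rose, and 13 fell and 1 rose when adjusted over the list alone. Cmklr1, the receptor of the adipokine chemerin, fell from 139 ± 19.7 to 54.8 ± 2.39 CPM (log2 fold change -1.34, SE 0.113, edgeR adjusted p = 0.00311), and the light-sensitive opsin Opn3 from 25.01 ± 3.02 to 7.36 ± 0.756 CPM (log2 fold change -1.76, SE 0.143, adjusted p = 0.00252). The cannabinoid receptor Cnr1 fell by 1.87, the fatty acid receptors Ffar2 and Ffar4 by 2.31 and 1.54 and the thyrotropin receptor Tshr by 1.56 on the log2 scale. Of the 4 further lists only this one passed camera with an estimated correlation (adjusted p = 0.00844, against 0.0686 for NRF2 targets and 0.125 for lysosomal genes and for carriers), and all 4 passed fry (highest adjusted p = 0.0358). The lists were written from these libraries and are not independent evidence. The 9 became 6 without control 3 or ANKO 1 and 5 without control 2, ANKO 2 or ANKO 3. Of 13 amino acid and solute carriers 4 fell and 1 rose, and 6 fell and 4 rose when adjusted over the list alone. The glutamate carrier Slc1a3 (186 ± 54.7 to 45.1 ± 0.932 CPM, log2 fold change -2.05, adjusted p = 0.0107) and the glutamine carrier Slc1a5 (1110 ± 186 to 458 ± 62.8 CPM, log2 fold change -1.28, adjusted p = 0.0107) fell with Slc7a10 and Slc16a7 (-1.21), while Slc43a2 rose (0.64). Of 40 lysosomal genes 5 rose and 18 when adjusted over the list alone, with Lipa, the lysosomal acid lipase, at 49.3 ± 3.20 and 116 ± 27.7 CPM (log2 fold change 1.23, adjusted p = 0.0205), followed by Ctsz (0.93), Creg1 (0.66), Lgmn and Atp6v0d2. Ctss and Lgmn also belong to the macrophage list, whose markers rose as well (list mean higher by 0.71, SE 0.133). The 5 lysosomal calls became 10 without ANKO 1 and 0 without any other 1 of the libraries. The 4 falls of carriers became 1 without ANKO 2 or ANKO 3, and 1 carrier rose without ANKO 1 and 0 rose without any other 1 of the libraries.

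The real split of the 6 libraries called 306 genes, and the highest count among the other 9 splits was 0 by edgeR, where 354 to 1120 genes had an unadjusted p under 0.05. Camera with the preset correlation called 22 lists in the real split and up to 20 in the others. In both cases 1 of the 10 splits, the real one, gave a result as large, and 10 splits are too few for a share under 0.05.

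Adipocyte genes were lower while macrophage and mast cell markers were higher. A lower share of adipocyte RNA alone would raise the markers of every other cell type alike. The list means differed by 0.91 (SE 0.171) for mast cell, 0.71 (SE 0.133) for macrophage, 0.19 (SE 0.116) for fibroblast, 0.03 (SE 0.139) for mural and -0.22 (SE 0.0824) for endothelial markers. The highest and the lowest lay 1.13 (SE 0.187) apart. These extremes were picked after the values were seen, without allowance for the choice, and mast cell markers are part of the pattern itself. The gap therefore cannot by itself exclude a lower adipocyte share as the only cause, although endothelial markers, outside the pattern, were lower and not higher. More macrophages of an unchanged kind and a changed state of macrophages both stay open. The 17 macrophage markers that were not called had a median log2 fold change of 0.44, against 3.27, 2.85, 1.00 and 0.72 for Gpnmb, Trem2, Adgre1 and Lgmn, but the markers were divided here by their own change, so the lower median decides nothing. The deletion itself remains a biological explanation that whole tissue could not test by cell type.

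Beside Adipoq, which fell, Rfc4 and Eif4a2 had positive log2 fold changes (0.94, SE 0.217, adjusted p = 0.0940, and 0.35, SE 0.0822, adjusted p = 0.102). ANKO mice carry an adiponectin-Cre transgene, and extra copies of the 100 kb on both sides of Adipoq, brought in with it, could raise the neighbouring genes together. The 5 neighbours of at least 1 CPM had a median log2 fold change of 0.11, at percentile 79.4 of 16687 sets of as many neighbouring genes. This leaves extra copies open, since the 5 went both ways, B630019A10Rik and BC106179 were close to 1 CPM and St6gal1 (-0.01, SE 0.138) extends beyond the window. Copies of 1 side alone were not tested, and the construct of the transgene is not given in the sources used here.

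Known targets of the oxidative stress factor NRF2 were among the rises. In a list of 30, of which Slc7a11 is also in the stress response list and Me1, G6pdx, Pgd and Tkt in the lipogenesis list, 8 rose, none fell, and 15 rose when adjusted over the list alone. They included Ephx1 (46.8 ± 1.07 to 133 ± 24.8 CPM, log2 fold change 1.51, SE 0.132, adjusted p = 0.00359), Hmox1 (21.2 ± 2.97 to 69.9 ± 16.9 CPM, log2 fold change 1.72, SE 0.198, adjusted p = 0.0107) and Ftl1 (398 ± 13.4 to 981 ± 230 CPM, log2 fold change 1.30, SE 0.173, adjusted p = 0.0134), whose count is uncertain where reads match its pseudogenes. The 22 members not called had a median log2 fold change of 0.19, 18 of them positive, but they were set apart by their own change, so this median decides nothing and a wider rise of NRF2 target genes may or may not extend beyond the 8. The 8 became 4 without ANKO 3.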
